A study of Oryctolagus cuniculus with 60 samples.

How the data were processed

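RNA was taken from the epithelium of rabbit skin and rabbit mucosa at 0 h, 12 h, 1 day, 3 days and 5 days after injury, and from unwounded skin. The labels call the 2 tissues cutaneous and mucosa and do not say which mucosa was sampled. Per the labels' protocols, the epithelium was cut away from the tissue beneath it with a blade, and total RNA was purified on columns and labelled with Cy3, so each array carried 1 sample in 1 colour. The array was a custom rabbit design with 4 arrays per slide and probes of 60 bases.

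Each deposited scanner file holds one spot per line with intensity values on a linear scale, written by the scanner maker's feature extraction program per the file headers. The processed intensity in these deposited files was background-subtracted by that program, and no scaling between arrays is recorded in the headers. The authors also deposited a table of processed values for the same 60 arrays, whose values are on a log2 scale as judged from the values. Its 60 columns had medians from 5.45 to 5.90 and correlated with the log2 processed intensity of the same array at 0.987 to 1.00 across 23369 probes. Their lower and upper quartiles nearly coincide, as quantile normalization would leave them, but their medians differ, so the kind of normalization stays uncertain. Probes were not centred. Whether the authors applied a further constant shift stays unknown, and their normalization program is not given in the sources used here. It served as an alternative.

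Each array had 45220 spots, of which 43553 were not controls, for 23369 probes. Of these probes 20184 were spotted at 2 places, and the log2 values of their spots were averaged. Between 31.5% and 53.5% of spots per array were well above background, and the 75th percentile of the processed intensity ran from 213 to 1582 between arrays. Duplicate spots on one array differed by a median of 0.0577 to 0.0924 in log2, so the number of samples limits the precision more than the spot noise does. At most 5 spots per array were saturated, and spots marked as outliers by the scanner program, at most 91 per array, were left out.

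The values analysed were log2 of the processed intensity minus log2 of the 75th percentile of that array over its non-control spots. A level of 0 is therefore the 75th percentile of the array. A probe was tested if it was well above background on at least 4 of the 60 arrays, which left 12473 probes. One linear model with a mean for each of the 11 groups was fitted per probe with lmFit and eBayes of limma 3.58.1 under R 4.3.3, and all groups shared one estimate of the spread. Tests were two-sided. A probe was called where its Benjamini-Hochberg adjusted p was under 0.05 and its change was at least 2-fold. Errors of changes are standard errors of that fit, and errors of levels are SDs between samples. Tables and figures were made with the R package data.table, version 1.17.8, and with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

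Groups and replicate numbers came from the sample labels. The series text calls the replicates biological, but neither it nor the labels say which samples came from one animal, so p-values measure the spread between these samples. The 4 arrays of unwounded skin differed pairwise by a median of 0.0961 in log2, close to the difference between duplicate spots of one array. The corresponding median was 0.220 to 0.435 in the other 10 groups. These 4 arrays were therefore averaged and counted as 1 sample, which makes 57 samples. This was decided after the data were examined, and keeping them as 4 samples is an alternative.

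Before the data were examined, 18 comparisons were fixed. They were mucosa against skin at each of the 5 times, each later time against 0 h within each tissue, the difference between those changes in mucosa and in skin (an interaction term) at each of the 4 later times, and skin at 0 h against unwounded skin. The 2 comparisons of 5 days with 12 h, one per tissue, were added after the data were examined.

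The files assign probes to assembled-transcript, clone or database identifiers, 16139 in all, with no gene name or description. Of these identifiers 447 are database entries, and 0 probes matched a symbol in the gene table at hand. The gene lists that had been fixed beforehand, and the tests on them, could not be run. The fixed rule for naming genes would have named none. In its place the 2 highest and the 2 lowest probes were named in each of 7 comparisons. Only the brightest tested probe of each identifier was considered, and identifiers that are database entries were left out. Probes were ranked by change among those with an adjusted p under 0.05 and, except for the interaction and for unwounded skin, no overlap of the groups in any array, which was decided after the values were seen. This gave 24 probes, which the text calls by their array names. No chromosome position is given because no genome was used here. For identifiers with 2 tested probes, of which there were 4182, changes at both probes correlated at 0.857 to 0.903 across identifiers, depending on the comparison.

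On an array where a probe was not well above background, its level has only an upper bound. If any array of the dimmer group was of this kind, the fold is given as "at least", from the brighter group's mean against the mean over the dim group's arrays. Each array without a measurement entered that mean with the higher of 2 values: the lowest signal of any probe well above background on that array, and the probe's own value. The log2 changes and interactions beside such folds are the fitted ones and are no bounds.

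Most alternatives replaced one choice. They were quantile normalization, scaling by the median of each array, normexp background correction with an offset of 50 followed by quantile normalization, no filter or a stricter filter on dim probes, the authors' table, slide as a random or a fixed block, a replicate block, a fit to the arrays of the comparison alone, unwounded skin as the baseline, the mean over the probes of an identifier, and leaving out each array in turn. Scan day as a block, the 75th percentile over the 5857 probes well above background on all arrays, leaving out the 3 dimmest arrays, and the unwounded arrays as 4 samples were added after the data were examined. The normexp alternative changed background correction and normalization together, and the slide and scan-day fits also kept the unwounded arrays as 4 samples, because their average lies on no single slide.

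The model was tested on simulated data for the 12473 probes with 200 changed probes per comparison. The noise was independent and normal, with an SD per probe pooled over all groups. Differences in spread between groups, such as the wider spread in mucosa at 5 days, were therefore not simulated. For mucosa against skin at 0 h it recovered 79% of simulated log2 changes of 1.5 and 97% of those of 3. For skin at 12 h against 0 h it recovered 88% and 97%, and for mucosa at 5 days against 0 h 85% and 98%. For the interaction at 1 day it recovered 61% and 89%, and for skin at 0 h against unwounded skin 40% and 87%.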

Results

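Expression was profiled in rabbit skin and mucosal epithelium on 60 single-colour arrays. Each tissue had 5 samples at 0 h, 6 each at 12 h, 1 day and 3 days after injury, and 5 at 5 days. A further 4 arrays, labelled unwounded skin at 0 h, differed pairwise by a median of 0.0961 (log2), near the highest median of 0.0924 between duplicate spots of one array, and were counted as 1 sample. The arrays lay on 15 slides scanned on 3 days. The skin and mucosa arrays at 0 h were scanned on day 1, the unwounded arrays on days 1 and 3, the 12 h arrays on days 1 and 2, the 1 day arrays on day 2, the 3 day arrays on days 2 and 3, and the 5 day arrays on day 3. Within groups of several samples, the median SD of a probe ran from 0.218 in skin at 0 h to 0.409 in mucosa at 5 days (log2). Levels are log2 intensities relative to the 75th percentile of the array.

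The comparison of mucosa with skin at 0 h asked how the 2 epithelia differ at the start of the series. The array names its probes without gene names, and the probes UF_Ocu_AF_111660 and UF_Ocu_AF_112686 were bright in mucosa and not well above background on any of the 5 skin arrays compared, though both were on all 4 arrays labelled unwounded skin, at 3.72 and 4.15. UF_Ocu_AF_111660 stood at 5.99 ± 1.18 in mucosa (SD, n = 5) and was at least 435-fold higher than in skin (log2 change 11.04 ± 1.03, adjusted p = 9.5e-13). UF_Ocu_AF_112686 stood at 4.42 ± 0.60 in mucosa (SD, n = 5) and was at least 147-fold higher (9.50 ± 0.63, adjusted p = 1.97e-17). In the other direction, UF_Ocu_AF_111509 was at least 202-fold lower in mucosa than in skin (fitted change -9.28 ± 0.49, adjusted p = 4.08e-21), and UF_Ocu_AF_110377 at least 117-fold lower (-8.35 ± 0.43, adjusted p = 1.9e-21). Each of these last 2 was well above background on 1 of 5 mucosa arrays and on 5 of 5 skin arrays. The sequence of UF_Ocu_AF_111660 is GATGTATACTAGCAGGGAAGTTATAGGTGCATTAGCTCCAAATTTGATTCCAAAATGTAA, and that of UF_Ocu_AF_112686 is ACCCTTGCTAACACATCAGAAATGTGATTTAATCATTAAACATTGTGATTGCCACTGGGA. A second probe for the transcript of UF_Ocu_AF_111509 gave a smaller change of -5.41 (adjusted p = 1.04e-18).

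In all, 3576 of 12473 tested probes were called at 0 h, 1650 higher in mucosa and 1926 lower, and all of these samples were scanned on 1 day. With scan day as a block the count was 3622, and with slide as a fixed block 3632. Each slide and scan day held as many mucosa as skin arrays of each time. These blocks therefore change the errors and not the estimated tissue differences. Skin arrays from 0 h to 5 days always lay at position 1 or 3 of a slide, and mucosa arrays at position 2 or 4. An effect of position on the slide therefore cannot be told apart from tissue. Background correction by normexp with quantile normalization gave a lower count of 2294. Among identifiers with 2 tested probes, 1425 had a call at either probe, 996 had the same call at both, and 9 had opposite calls.

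The tissues were then compared at each time after injury. The 4 probes named at 0 h kept their directions throughout: UF_Ocu_AF_111660 was at least 134-fold higher in mucosa at 12 h and 133-fold at 5 days, and UF_Ocu_AF_112686 at least 33.5-fold and 94.3-fold higher. UF_Ocu_AF_111509 was at least 96.5-fold and 121-fold lower at these times, and UF_Ocu_AF_110377 at least 16.4-fold and 64.8-fold lower. The largest adjusted p of these 8 values was 6.12e-09. In the dimmer tissue, UF_Ocu_AF_111660 was well above background on 1 of 6 arrays at 12 h and 1 of 5 at 5 days, UF_Ocu_AF_112686 on 0 of 6 and 0 of 5, UF_Ocu_AF_111509 on 1 of 6 and 0 of 5, and UF_Ocu_AF_110377 on 0 of 6 and 1 of 5. Of 6418 probes called at any of the 5 times, 740 were higher in mucosa at all 5 times, 453 were lower at all 5 times, and 114 were called in both directions at different times.

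The number called between the tissues was 3972 at 12 h (1903 higher in mucosa, 2069 lower), 4019 at 1 day (1902 and 2117), 2735 at 3 days (1308 and 1427) and 2739 at 5 days (1429 and 1310). The counts with scan day as a block were 4014, 4060, 2800 and 2814, and with slide as a fixed block 4021, 4061, 2804 and 2829. By the same balance, these blocks change only the errors. Within one scan day the counts were 3643 on day 1 and 623 on day 2 at 12 h, 4137 on day 2 at 1 day, 4646 on day 2 and 2112 on day 3 at 3 days, and 2488 on day 3 at 5 days. The day 2 values at 12 h and 3 days rest on 2 samples per tissue. When a slide was left out of the calls, 88.0% to 99.4% of them had the same sign on that slide at 12 h, 74.5% to 99.8% at 1 day, 79.9% to 99.1% at 3 days and 92.3% to 95.2% at 5 days, with the lowest values on slide 7 at 12 h, slide 10 at 1 day and slide 13 at 3 days. The balance of directions depended on the scaling. With the 75th percentile taken over the probes above background on all arrays, the higher and lower calls were 2546 and 1148 at 12 h, 2583 and 1203 at 1 day, 1649 and 1031 at 3 days, and 1680 and 1004 at 5 days. Scaled by the median, they were 1616 and 2757 at 12 h and 1532 and 3247 at 1 day. By normexp with quantile normalization they were 1372 and 905 at 12 h, 1496 and 960 at 1 day, and 1068 and 707 at 3 days, with 1725 calls at 5 days. Without the filter on dim probes, 6068 probes were called at 1 day. The median change of all probes at 1 day was -0.23 in the main setting, -0.47 by the median and 0.10 by the probes above background on all arrays.

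**Figure D1:**
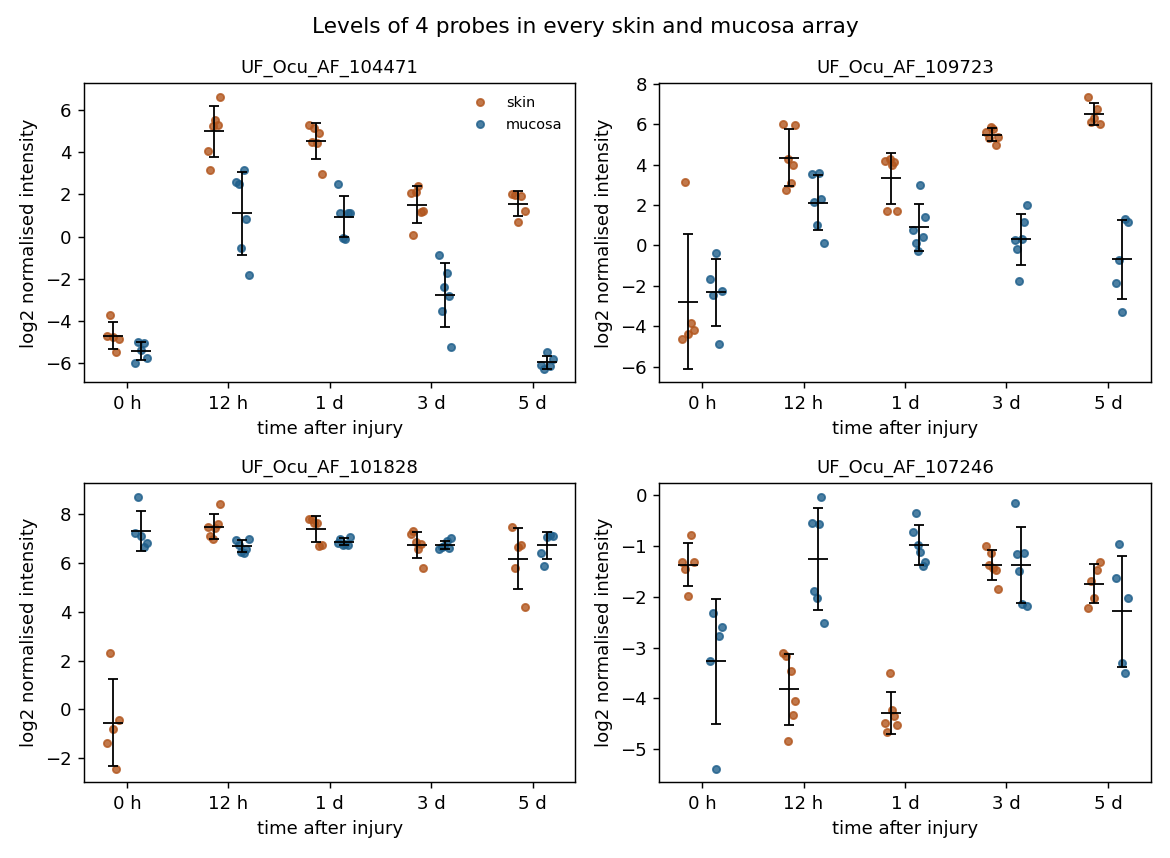
Levels of 4 probes on each skin and mucosa array (vertical axes, log2 intensity relative to the 75th percentile of the array) against time after injury (horizontal axes). Points are single arrays, and bars are the mean and SD of each group. UF_Ocu_AF_104471 reached 4.98 ± 1.21 in skin and 1.10 ± 1.97 in mucosa at 12 h, UF_Ocu_AF_101828 was low only on the skin arrays at 0 h, at -0.54 ± 1.77, and UF_Ocu_AF_109723 had 1 bright skin array at 0 h.

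The skin wounds were compared with skin at 0 h to describe the response to injury over time. At 12 h, UF_Ocu_AF_104471 rose from background to 4.98 ± 1.21 (SD, n = 6), at least 216-fold (log2 change 9.66 ± 0.64, adjusted p = 4.21e-17). UF_Ocu_AF_110525 rose at least 168-fold (9.22 ± 0.66, adjusted p = 5.07e-16), to 4.61 ± 0.66 (SD, n = 6). Neither was well above background on any of the 5 skin arrays at 0 h. UF_Ocu_AF_107673 fell at least 27.1-fold (fitted change -4.94 ± 0.38, adjusted p = 7.1e-15) and was well above background on 2 of 6 arrays at 12 h. UF_Ocu_AF_101153 fell 19.1-fold (-4.26 ± 0.35, adjusted p = 4.63e-14), from 3.50 ± 0.31 (SD, n = 5) to -0.76 ± 0.66 (SD, n = 6). The sequence of UF_Ocu_AF_104471 is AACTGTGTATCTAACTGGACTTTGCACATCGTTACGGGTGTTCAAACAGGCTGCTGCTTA, and that of UF_Ocu_AF_110525 is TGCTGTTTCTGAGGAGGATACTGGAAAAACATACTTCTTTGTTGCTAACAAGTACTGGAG. With the unwounded sample as the baseline, the changes of UF_Ocu_AF_104471 and UF_Ocu_AF_110525 were smaller, at 3.15 (adjusted p = 0.0456) and 2.78 (adjusted p = 0.0833).

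At 5 days, UF_Ocu_AF_108489 and UF_Ocu_AF_109723 rose at least 226-fold and 259-fold in skin, with fitted log2 changes of 9.47 ± 0.84 (adjusted p = 3.99e-12) and 9.29 ± 0.97 (adjusted p = 3.09e-10). Both were well above background on 1 of 5 skin arrays at 0 h, replicate 2. Without that array no 0 h array measured them, and the rises were at least 409-fold and 582-fold. UF_Ocu_AF_104471 was still at least 20.3-fold above 0 h at 5 days (6.25 ± 0.67, adjusted p = 6.56e-10), but at 1.57 it was not above the unwounded sample, which stood at 1.83. Among probes that fell, UF_Ocu_AF_103099 changed by -4.42 ± 0.59 (adjusted p = 1.35e-07) and UF_Ocu_UN_119795 by -3.97 ± 0.53 (adjusted p = 1.69e-07, at least 5.97-fold lower, not well above background on any array at 5 days). Against the unwounded sample these changes at 5 days were 2.79, 2.90, 1.01 and -0.99 for UF_Ocu_AF_108489, UF_Ocu_AF_109723, UF_Ocu_AF_103099 and UF_Ocu_UN_119795, with adjusted p of 0.267, 0.319, 0.576 and 0.543. The direction of UF_Ocu_AF_103099 thus turned with the baseline, and none of the 4 passed the threshold.

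**Figure D2:**
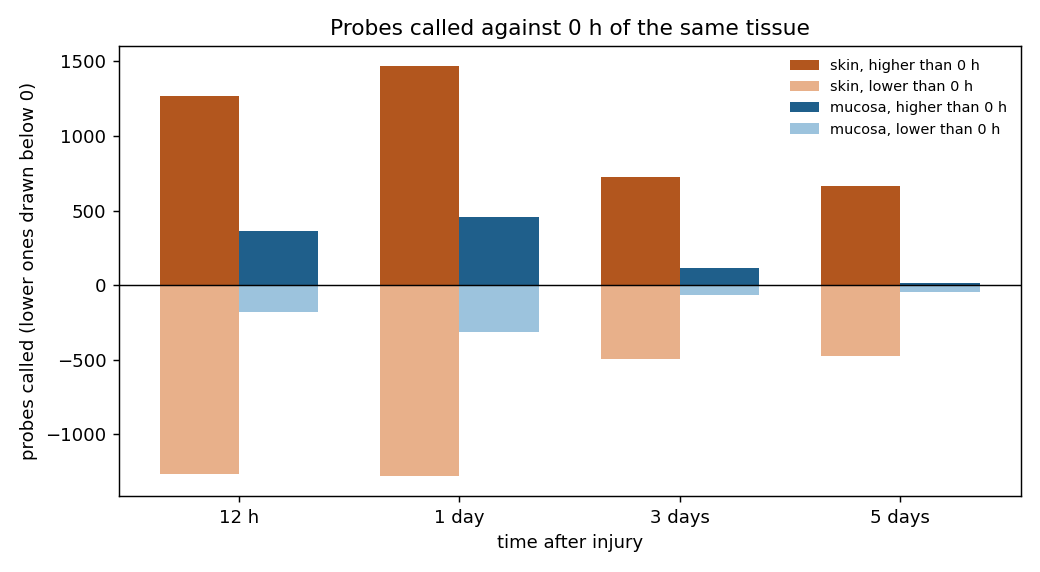
Number of probes called against 0 h of the same tissue (vertical axis, with lower probes drawn below 0) at each time after injury (horizontal axis), for skin and mucosa. The counts of higher and lower probes were 1466 and 1277 in skin and 458 and 312 in mucosa at 1 day, and 664 and 476 in skin and 14 and 44 in mucosa at 5 days.

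In skin, 2535 probes were called at 12 h (1270 higher, 1265 lower), 2743 at 1 day (1466 and 1277), 1223 at 3 days (727 and 496) and 1140 at 5 days (664 and 476). With scan day as a block the counts were 2551, 2616, 1079 and 1035, with slide as a fixed block 2451, 2198, 678 and 1043, and on scan day 1 alone 2406 at 12 h. At 1 day, 3 days and 5 days no scan day held both the wounded and the 0 h samples. By normexp with quantile normalization the counts were 1550, 1581, 672 and 680, and with the unwounded sample as the baseline 573 at 5 days (166 higher, 407 lower). The directions depended on the scaling. With the 75th percentile over the probes above background on all arrays, 793 were higher and 2038 lower at 12 h, 804 and 2653 at 1 day, 534 and 788 at 3 days, and 526 and 713 at 5 days, while by the median 2322 were higher and 777 lower at 1 day. The median change of all probes at 1 day was 0.00 in the main setting, -0.39 by the former and 0.31 by the latter.

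In mucosa, UF_Ocu_AF_104471 and UF_Ocu_AF_109723 also rose at 12 h. UF_Ocu_AF_104471 rose at least 19.1-fold (log2 change 6.53 ± 0.64, adjusted p = 1.29e-09), from background on all 5 arrays at 0 h to 1.10 ± 1.97 (SD, n = 6), and was not well above background on any of 5 arrays at 5 days. UF_Ocu_AF_109723 rose at least 16.2-fold (fitted change 4.45 ± 0.93, adjusted p = 9.54e-04, well above background on 4 of 5 arrays at 0 h), and the fitted change was 3.81 without mucosa 0 h replicate 4. UF_Ocu_AF_102970 fell 10.8-fold (-3.43 ± 0.61, adjusted p = 1.28e-04), from 2.50 ± 0.50 (SD, n = 5) to -0.93 ± 1.02 (SD, n = 6). UF_Ocu_AF_108529 fell 6.97-fold (-2.80 ± 0.67, adjusted p = 3.78e-03), a call lost with slide as a fixed block (-2.25, adjusted p = 0.0687). At 5 days, UF_Ocu_AF_113948 was at least 9.09-fold lower than at 0 h (-3.18 ± 0.46, adjusted p = 8.57e-05, well above background on 2 of 5 arrays at 5 days). With scan day as a block its change was -2.46 (adjusted p = 0.053), and with slide as a fixed block -1.79 (adjusted p = 0.227). UF_Ocu_AF_109112 was at least 5.26-fold lower (fitted change -3.11 ± 0.73, adjusted p = 0.0281, well above background on 2 of 5 arrays at 5 days). Its call was lost in 8 of 25 alternatives (adjusted p up to 0.404), among them those without mucosa 0 h replicates 2 and 4 (-3.17 and -2.30) and mucosa 5 day replicates 3 and 4 (-2.83 and -2.71). UF_Ocu_UN_118606 rose 2.00-fold (1.00 ± 0.23, adjusted p = 0.0268), a call lost in 11 of 25 alternatives (adjusted p up to 0.464), among them those without mucosa 0 h replicates 2, 3 and 4 (0.97, 0.88 and 0.99) and mucosa 5 day replicates 1, 3 and 4 (0.97, 0.92 and 0.91). UF_Ocu_UN_122269 had a fitted change of 1.31 ± 0.34 (adjusted p = 0.0465) from background on all 5 arrays at 0 h, a call lost in 16 of 25 (adjusted p up to 0.347), also without mucosa 0 h replicates 2, 3 and 4 (1.24, 1.20 and 1.30) and mucosa 5 day replicates 1 to 5 (1.43, 1.25, 1.24, 1.29 and 1.33).

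In mucosa, 544 probes were called at 12 h (363 higher, 181 lower), 770 at 1 day (458 and 312), 179 at 3 days (113 and 66) and 58 at 5 days (14 and 44). With scan day as a block the counts were 641, 282, 199 and 50, with slide as a fixed block 404, 142, 62 and 40, and on scan day 1 alone 600 at 12 h. Fitted to the arrays of each comparison alone, 303 were called at 12 h, 2 at 3 days and 2 at 5 days. Scaled by the median, 509 were higher and 176 lower at 1 day, 1 and 41 at 5 days, and 100 were called at 3 days. With the percentile over the probes above background on all arrays, 379 were higher and 459 lower at 1 day, and by normexp with quantile normalization 298 and 90, with 348 called at 12 h. Quantile normalization alone gave 90 at 5 days, the unwounded arrays as 4 samples gave 98, and no filter on dim probes gave 99 at 3 days and 27 at 5 days.

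Single mucosa arrays moved these counts by over 1.5 times. At 12 h, 923 probes were called without mucosa 12 h replicate 6. At 3 days the count was 61 without mucosa 0 h replicate 2, 105 without replicate 3, 306 without replicate 5, 84 without mucosa 3 day replicate 1 and 94 without its replicate 2. At 5 days it was 188, 12, 21, 24 and 220 without mucosa 0 h replicates 1 to 5 in turn, and 27, 26 and 38 without mucosa 5 day replicates 1, 3 and 4.

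Changes in the 2 tissues were set side by side, using separate 0 h samples. The probes called higher in skin had median log2 changes of 1.51, 1.46, 1.56 and 1.69 in skin at 12 h, 1 day, 3 days and 5 days. The same probes had medians of 0.55, 0.40, 0.36 and 0.23 in mucosa. They were chosen by their change in skin, which raises the skin medians, so part of the gap to mucosa is fixed by the choice. At 12 h, 221 probes were called higher in both tissues, against 36.96 for independent lists, and 99 lower in both, against 18.4, while 24 were called in opposite directions. At 5 days, 2 were higher in both, against 0.75, and 19 lower in both, against 1.68. Skin and mucosa arrays of each time shared slides and scan days. A shift common to a slide or day could therefore add to these overlaps and to the correlations that follow. Across probes, which are not independent, the changes in skin and mucosa correlated at 0.487, 0.413, 0.383 and 0.256 at the 4 times. The correlations with scan day as a block were 0.499, 0.473, 0.594 and 0.596, and with slide as a fixed block 0.539, 0.492, 0.670 and 0.670, but in those fits both tissues share the estimated difference between days or slides.

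The interaction term tested whether the change in mucosa differed from that in skin. At 1 day, UF_Ocu_AF_101828 had a negative interaction (-8.38 ± 0.64, adjusted p = 1.07e-13), and UF_Ocu_AF_101829, the other probe of its transcript, one of -9.90 (adjusted p = 1.79e-13). UF_Ocu_AF_101828 rose in skin by 7.93 ± 0.46, from -0.54 ± 1.77 (SD, n = 5) to 7.40 ± 0.53 (SD, n = 6), and stood at 7.32 ± 0.82 (SD, n = 5) in mucosa at 0 h and 6.87 ± 0.14 (SD, n = 6) at 1 day. Without skin 0 h replicate 2 its interaction was -9.09. The unwounded sample stood at 6.93 for this probe, near skin at 1 day, so the rise and the interaction rest on skin at 0 h as the baseline. For UF_Ocu_AF_105736 it stood at 4.97, between skin at 0 h (-1.81) and at 1 day (7.31), for UF_Ocu_AF_107246 at -1.42, near skin at 0 h (-1.37), and for UF_Ocu_UN_122905 at -1.66, between skin at 0 h (0.17) and at 1 day (-2.61). UF_Ocu_AF_105736 rose at least 484-fold in skin (fitted change 9.13 ± 0.70, well above background on 4 of 5 arrays at 0 h) and changed by 1.73 ± 0.70 in mucosa (adjusted p = 0.0731), an interaction of -7.39 ± 0.99 (adjusted p = 1.95e-07). That value was -6.71 without mucosa 0 h replicate 1, -8.44 without its replicate 4 and -6.78 without skin 0 h replicate 4. UF_Ocu_AF_107246 went the opposite way in the 2 tissues, falling in skin at least 2.13-fold (adjusted p = 1.96e-07) and rising in mucosa at least 3.58-fold (adjusted p = 3.11e-04), with a fitted interaction of 5.22 ± 0.61 (adjusted p = 9.47e-09). It was well above background on 0 of 6 skin arrays at 1 day and on 3 of 5 mucosa arrays at 0 h. For UF_Ocu_UN_122905 the fitted interaction was 4.73 ± 1.04 (adjusted p = 5.97e-04, well above background on 2 of 6 skin arrays at 1 day and 2 of 5 mucosa arrays at 0 h), and 5.38 without mucosa 0 h replicate 3. UF_Ocu_AF_104471 had a smaller fitted rise in mucosa than in skin at 12 h, with a fitted interaction of -3.13 ± 0.90 (adjusted p = 0.0117). Its fitted interaction at 5 days was -6.77 ± 0.94 (adjusted p = 2.26e-06), where mucosa had no measured rise. It was well above background on 0 of 5 arrays at 0 h in each tissue and on 0 of 5 mucosa arrays at 5 days.

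The interaction was called for 1371 probes at 12 h (745 higher, 626 lower), 1867 at 1 day (844 and 1023), 542 at 3 days (169 and 373) and 511 at 5 days (150 and 361). As a block, scan day gave 1469, 2000, 632 and 606, and slide as a fixed block gave 1516, 2052, 693 and 685. Skin and mucosa arrays were balanced over slides and days, so these blocks change only the errors of the interactions. On scan day 1 alone 1073 were called at 12 h. Scaled by the median, higher and lower calls were 498 and 734 at 12 h, 537 and 1562 at 1 day, 131 and 209 at 3 days, and 65 and 340 at 5 days. With the percentile over the probes above background on all arrays they were 1118 and 363, 1399 and 524, 258 and 277, and 221 and 281. By normexp with quantile normalization, 909 were called at 12 h and 1150 at 1 day (651 higher, 499 lower), and with the arrays of the comparison alone 331 at 5 days.

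Skin at 0 h was compared with the sample labelled unwounded skin. In skin at 0 h, UF_Ocu_AF_112686 was at least 121.5-fold lower than in the unwounded sample (log2 change -9.23 ± 1.10, adjusted p = 3.03e-08) and UF_Ocu_AF_107034 at least 134-fold lower (-9.05 ± 0.96, adjusted p = 1.61e-09). Both were also bright in mucosa at 0 h, at 4.42 ± 0.60 and 3.62 ± 1.34 (SD, n = 5), and not well above background on any skin array from 0 h to 5 days other than those labelled unwounded. In the other direction, UF_Ocu_AF_103099 was 42.9-fold higher in skin at 0 h (5.42 ± 1.02, adjusted p = 1.5e-04), and UF_Ocu_AM_114944 at least 6.06-fold higher (4.56 ± 1.14, adjusted p = 3.96e-03). The unwounded sample correlated across probes at 0.885 with the mean of skin at 0 h, 0.962 with mucosa at 0 h and 0.982 with mucosa at 3 days.

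Of the tested probes, 1858 were called between skin at 0 h and the unwounded sample, 1008 higher and 850 lower. The single unwounded sample was assumed to vary like the other groups. With its 4 arrays as 4 samples the count was 3661, and then also with scan day as a block 4002, with slide as a fixed block 3811 and as a random block 3689, and with the arrays of the comparison alone 3531.

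**Figure D3:**
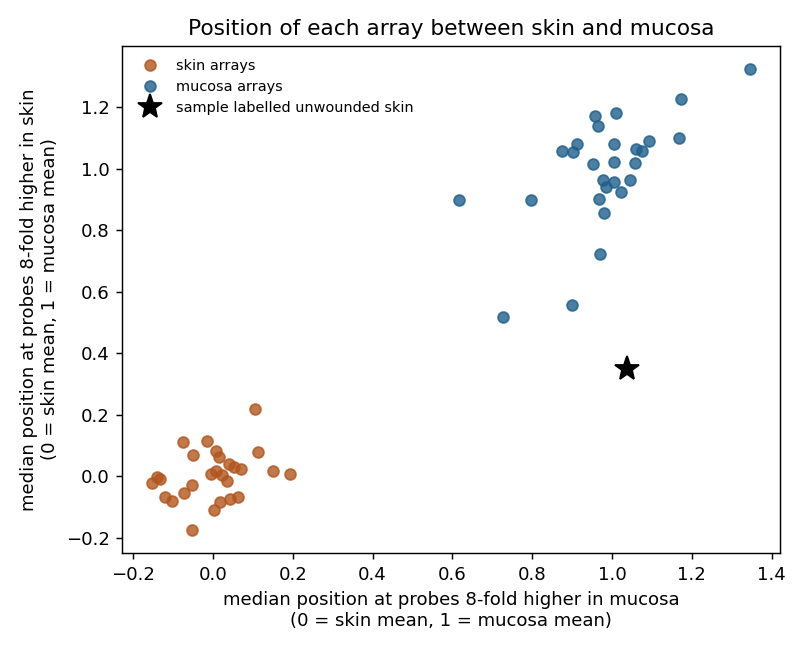
Position of each array between the mean of skin (0) and the mean of mucosa (1), without units, as a median over probes at least 8-fold higher in mucosa (horizontal axis) and over probes at least 8-fold higher in skin (vertical axis). The star is the sample labelled unwounded skin, at 1.04 over 176 probes and 0.348 over 63 probes. Points are single skin and mucosa arrays, each set against means made without it. The points rest on other probe sets, of 144 to 163 and 41 to 47 probes, so star and points are only roughly comparable. The skin arrays lie between -0.15 and 0.19 on the horizontal axis, and the mucosa arrays between 0.62 and 1.35.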

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

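The test of the spread between mucosa samples was chosen only after the result was seen, while the test on dim probes was fixed before its result was seen. In 78 groups of values of named probes or of array quality, 12 had 1 sample far from the others. Chance alone sets apart 1 in 20 such groups, or 3.9 of 78.

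On single arrays, UF_Ocu_AF_111509 was highest in mucosa 0 h replicate 1, at -2.25 against -5.04 ± 0.36 in the other 4 samples. UF_Ocu_AF_108489 was highest in skin 5 day replicate 1, at 7.41 against 5.64 ± 0.19 in the others, and in skin 0 h replicate 2, at 1.60 against -4.74 ± 0.20. UF_Ocu_AF_109723 was also highest in skin 0 h replicate 2, at 3.15 against -4.27 ± 0.34. UF_Ocu_AF_107246 was highest in skin 1 day replicate 3, at -3.51 against -4.45 ± 0.17, where no array of the group was well above background. UF_Ocu_AF_101828 was highest in mucosa 0 h replicate 2, at 8.72 against 6.97 ± 0.27, and UF_Ocu_AM_114944 in skin 0 h replicate 5, at -0.18 against -0.67 ± 0.07. UF_Ocu_AF_105736 was lowest in skin 0 h replicate 4, at -4.26 against -1.20 ± 0.41. Values are log2 levels, each with the mean and SD of the others.

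Mucosa 0 h replicate 2 had the dimmest array of its group, with a 75th percentile of 213 intensity units against 891 ± 34.9 in the other 4. The share of spots well above background was lowest in mucosa 3 day replicate 5, at 34.0% against 45.7% ± 2.39, and in skin 3 day replicate 6, at 31.5% against 45.2% ± 1.66. It was highest in skin 1 day replicate 6, at 44.6% against 37.7% ± 0.71.

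The change after injury differed between mucosa and skin by the interaction test at 1371 probes at 12 h, 1867 at 1 day, 542 at 3 days and 511 at 5 days. At 1 day, the named probes had interactions of 5.22 for UF_Ocu_AF_107246, 4.73 for UF_Ocu_UN_122905, -8.38 for UF_Ocu_AF_101828 and -7.39 for UF_Ocu_AF_105736. Among 100 groupings of the samples at each time, the real one included, only the real one gave as many calls (1 of 100). The highest other grouping gave 1107 at 12 h, 1582 at 1 day, 127 at 3 days and 57 at 5 days. This argues against chance assignment of samples at these 4 times, though 100 groupings cannot show less than 1 of 100.

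The response was smaller in mucosa than in skin. The SD of log2 changes over all tested probes, after the standard errors were taken out, was 0.972, 0.976, 0.687 and 0.702 in skin at 12 h, 1 day, 3 days and 5 days, and 0.522, 0.558, 0.357 and 0.326 in mucosa. A wider spread between mucosa samples could hide equal changes, but the ratio of mucosa to skin, at most 0.6605 with any array left out, stayed below the 1 that this would need. Dim probes could inflate the changes in skin, but among the 5857 probes well above background on all arrays the ratio was at most 0.511. A biological difference between the tissues stays open as a hypothesis, as does a difference in the extent of injury or in how the epithelium was separated, and neither was tested. The state of skin at 0 h, on which each of these skin SDs rests, stays open as well. Between 12 h and 5 days, a comparison without 0 h samples, the SD was 0.645 in skin and 0.431 in mucosa. No scan day held both of those times, and these SDs were not recomputed with arrays left out. Skin at 0 h differed from the unwounded sample at 1858 probes, and the SD was not computed against that sample.

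Other groupings were also counted for the comparisons within and between tissues. For mucosa against skin, 1 of 100 groupings, the real one, gave as many calls at each time, with 3576 real calls and at most 1567 in any other at 0 h, 3972 and 2502 at 12 h, 4019 and 2505 at 1 day, 2735 and 1850 at 3 days, and 2739 and 1574 at 5 days. The same held in skin, with 2535 and 2274 at 12 h, 2743 and 2081 at 1 day, 1223 and 334 at 3 days, and 1140 and 395 at 5 days, and in mucosa at 1 day, with 770 and 239. In these comparisons only the real grouping gave as many calls, which argues against chance as far as 100 groupings can show. The groupings mixed scan days and exclude no effect of scan day. In mucosa at 12 h, 3 of 100 groupings gave 544 or more, and the highest other gave 832, which argues against chance less strongly and does not exclude it. Chance was not excluded in mucosa at 3 days, where 7 of 100 groupings gave 179 or more and another gave 713, nor at 5 days, where 8 of 100 gave 58 or more and another gave 566. Other groupings with several times the real count point to differences among these mucosa samples that their time after injury does not account for.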

How the results depend on the processing

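The percentile over probes above background on all arrays, scan day as a block, the unwounded arrays as 4 samples and the fits without the 3 dimmest arrays were chosen after the data were examined, and the comparisons of 5 days with 12 h were added then. Under a stricter filter on dim probes, the authors' table, the fits without the 3 dimmest arrays and the percentile over probes above background on all arrays, each total stayed within 1.5 times its main value, but higher and lower counts moved further by that percentile (804 and 2653 in skin at 1 day). The cause was not tested where a value below moved. Gene list medians were not run, since no probe had a gene name. Detection limits results: 31.5% to 53.5% of spots per array were well above background.

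By normexp with quantile normalization, the counts for mucosa against skin were 2294 at 0 h, 2277 at 12 h, 2456 at 1 day, 1775 at 3 days and 1725 at 5 days, those in skin were 1550, 1581, 672 and 680 at the 4 later times, those in mucosa were 348 at 12 h and 388 at 1 day, the interactions were 909 at 12 h and 1150 at 1 day, and skin at 5 days against 12 h gave 810. Scaling by the median gave 100 for mucosa at 3 days, 340 for the interaction at 3 days and 205 for mucosa at 5 days against 12 h. Without the filter on dim probes the counts were 6068 for mucosa against skin at 1 day, 99 and 27 for mucosa at 3 and 5 days, and 201 for mucosa at 5 days against 12 h, and the correlation of the changes in both tissues at 1 day was 0.3525. Quantile normalization gave 90 for mucosa at 5 days.

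With the arrays of the comparison alone, the counts were 303, 2 and 2 for mucosa at 12 h, 3 days and 5 days, 29 for mucosa at 5 days against 12 h, 331 for the interaction at 5 days and 3531 for skin at 0 h against unwounded skin. With scan day as a block, the latter count was 4002, mucosa at 1 day gave 282 and mucosa at 5 days against 12 h gave 32, and the correlations were 0.4734, 0.5936 and 0.5962 at 1 day, 3 days and 5 days. With slide as a fixed block, the counts were 3811 for skin at 0 h against unwounded skin, 678 for skin at 3 days, 142 and 62 for mucosa at 1 day and 3 days, 953 and 12 for 5 days against 12 h in skin and mucosa, and the correlations were 0.4916, 0.6704 and 0.6703. Both tissues share the estimated batch difference there, which by construction adds to the correlation. With slide as a random block (correlation within slides 0.0844), skin at 0 h against unwounded skin gave 3689. The unwounded arrays as 4 samples gave 3661 there and 98 for mucosa at 5 days, and unwounded skin as the baseline gave 573 for skin at 5 days and turned UF_Ocu_AF_103099 to 1.01 (1.0053, adjusted p = 0.576).

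Of 28 pairs of same-numbered skin and mucosa samples, 19 had deviations from their group means that correlated above 0.1 (range -0.31 to 0.41), and 14 mucosa samples correlated best with the skin sample of their own number, against 5 by chance. They share slides too, and as 9 pairs did not exceed 0.1, the numbers were not taken as pairs. The replicate block took different forms. For mucosa against skin and the interactions, each pair of same-numbered samples at a given time was a block. Mucosa against skin then gave 3602, 3987, 4019, 2748 and 2765 calls at the 5 times, and the interactions 1418, 1967, 581 and 570. For changes within a tissue, samples of equal number shared a block across times and tissues, although no label links them across times. Skin then gave 2571, 2760, 1243 and 1164, and mucosa 673, 882, 238 and 71. The comparison of 5 days with 12 h gave 1586 in skin and 434 in mucosa. No count moved by over 1.5 times, and the comparison with the 1 unwounded sample could not be fitted.

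With each array left out in turn, the counts for mucosa against skin ranged from 3374 to 3704 at 0 h, 3760 to 4340 at 12 h, 3766 to 4413 at 1 day, 2489 to 3179 at 3 days and 2368 to 2949 at 5 days. They ranged in skin from 2405 to 2738, 2675 to 2833, 1097 to 1240 and 886 to 1288, in mucosa from 378 to 923, 594 to 884, 61 to 306 and 12 to 220, and for the interactions from 1251 to 1558, 1731 to 2000, 443 to 605 and 359 to 624 at the 4 later times. Skin at 0 h against unwounded skin ranged from 1664 to 1883, and 5 days against 12 h from 1372 to 1843 in skin and 117 to 754 in mucosa. The correlations ranged from 0.4496 to 0.5073, 0.3891 to 0.4261, 0.3464 to 0.4055 and 0.2205 to 0.2755. The mucosa counts that moved by over 1.5 times were 923 at 12 h without mucosa 12 h replicate 6; 61, 105, 306, 84 and 94 at 3 days without mucosa 0 h replicates 2, 3 and 5 and mucosa 3 day replicates 1 and 2; 188, 12, 21, 24, 220, 27, 26 and 38 at 5 days without mucosa 0 h replicates 1 to 5 and mucosa 5 day replicates 1, 3 and 4; and 117, 185, 201, 195, 754, 713, 136 and 189 for 5 days against 12 h without mucosa 12 h replicates 1, 2, 4, 5 and 6 and mucosa 5 day replicates 2, 3 and 4.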

Other observations

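The comparisons of 5 days with 12 h, and the 4 tests of why the unwounded sample lay near mucosa, were chosen after the data were examined. The 3 tests on probes that rise in skin wounds were fixed before their results were seen.

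Probe UF_Ocu_AF_104471, which rose in both tissues at 12 h, had fallen by 5 days. In skin its log2 change from 12 h to 5 days was -3.41 ± 0.64 (adjusted p = 3.73e-05), to a level of 1.57 ± 0.59 (SD, n = 5). In mucosa it was at least 26.9-fold lower at 5 days than at 12 h (-7.05 ± 0.64, adjusted p = 9.15e-11) and not well above background on any of 5 arrays at 5 days. UF_Ocu_AF_110525 changed by -1.76 ± 0.66 in skin (adjusted p = 0.0355) and was at least 8-fold lower at 5 days in mucosa (fitted change -3.69 ± 0.66, adjusted p = 5.45e-04, 2 of 5 arrays well above background at 5 days). UF_Ocu_AF_109723 changed by 2.15 ± 0.93 in skin (adjusted p = 0.0732) and -2.80 ± 0.93 in mucosa (adjusted p = 0.0586), neither past the threshold.

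Between 12 h and 5 days, 1537 probes were called in skin (940 higher at 5 days, 597 lower) and 329 in mucosa (120 and 209). Of 100 groupings, the real one included, 1 gave as many as the real 1537 in skin, with at most 1254 in any other, which argues against chance there. In mucosa 3 gave as many as 329, and another gave 1153, which points to a structure among these mucosa samples other than time. The groupings mixed scan days, and no scan day held both 12 h and 5 day samples, so scan day stays open. The mucosa count was 117, 185, 201, 195 and 754 without mucosa 12 h replicates 1, 2, 4, 5 and 6, and 713, 136 and 189 without mucosa 5 day replicates 2, 3 and 4. With slide as a fixed block it was 12, and with scan day as a block 32. The skin count was 953 with slide as a fixed block (456 higher, 497 lower) and 1358 with scan day as a block. With the percentile over the probes above background on all arrays, 1193 were higher and 426 lower in skin and 172 and 196 in mucosa, and by the median 40 and 165 in mucosa.

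The sample labelled unwounded skin lay nearer to mucosa than to skin at 0 h, with a root mean square log2 difference of 0.755 to mucosa at 0 h, 1.36 to skin at 0 h and 0.522 to mucosa at 3 days. At 176 probes at least 8-fold higher in mucosa at all 4 wound times, its median position from skin (0) to mucosa (1) was 1.0366. At 63 probes higher in skin its position was 0.3483. The single skin and mucosa arrays were placed over other probe sets, each against means made without that array. These sets held 144 to 163 probes higher in mucosa and 41 to 47 higher in skin. Over them the skin arrays lay at -0.15 to 0.19 and -0.18 to 0.22. The mucosa arrays lay at 0.62 to 1.35 and 0.52 to 1.32. Because probe sets and means differed, these ranges are only a rough guide to where the unwounded sample lay. The sets of 176 and 63 probes were chosen on injured skin, so probes that injury had lowered or raised there would also enter them. Injury as the reason for the distance from skin stays open. Slide and scan day are argued against: its arrays on 2 slides, scanned on different days, differed by a median of 0.092, against 0.630 to skin at 0 h. A weighted sum of the other groups had a share of 0.844 of its weight on mucosa. That share lay on wounded mucosa (0.391 at 1 day, 0.197 at 12 h, 0.152 at 5 days and 0.103 at 3 days). Mucosa at 0 h had a weight of 0. The error of the sum on held-out probes was 0.3359. The median distance of a single array from the others of its group was 0.373 in skin at 0 h and 0.657 in mucosa. Those distances involve no fitted weights and no averaged arrays, so they are only a loose yardstick. Mucosal RNA in this sample may be the source, by mixing or labelling, which stays a hypothesis. A difference between body sites of skin also stays open, untested.

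Probes that rose in skin at 12 h were often higher in mucosa than in skin at 0 h. To keep the comparisons apart, the 5 skin 0 h arrays were split in all 10 ways, with 3 for the wound response and 2 for the tissue difference. Of the rising probes, 23.3% to 25.3% were at least 2-fold higher in mucosa at 0 h, of the falling ones 11.2% to 14.6%, and of all tested probes 14.6% to 15.8%. At most 25.159% of the probes at least 8-fold higher in mucosa rose in skin. This argues against mucosal RNA in the wounded skin samples at a share large enough to raise nearly all of these probes. A smaller share would bring only the probes with the largest difference past the 2-fold threshold, and the percentage cannot exclude it. No skin array served both comparisons in a split, so chance values of single arrays would give a ratio of rising to all probes near 1. The lowest ratio was 1.4962, which argues against such values as the whole reason, although it just missed the bound of 1.5 that had been set. A difference common to all skin 0 h samples enters both comparisons in any split and stays open. That wounded skin takes on part of the expression of mucosa may be proposed as a hypothesis, with a lowest difference of 9.047 percentage points between rising and falling probes, but it cannot be told apart from probes that are low in skin at 0 h for other reasons.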
